A study of Mus musculus with 10 samples.

How the data were processed

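RNA was extracted with a column kit from mature Chat+ and Chat- B cells sorted by flow cytometry, and libraries were made with a strand-specific Illumina kit, per the labels' protocols. Reads were trimmed with cutadapt 2.6 and quantified with Salmon 0.14.2, with the genome build GRCm38.p6, per the submitters' processing notes. The transcript annotation, the Salmon strand setting and the tool that made the CPM values are not given in the sources used here. Each library is 1 column of the table, mapped to its sample by the column name, and no column was left over.

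The deposited values are log2 values, although the table is named for normalized counts. All 10 libraries share the same lowest value, -3.1228, and the values with that offset (0.1148 CPM) removed sum to 1000000 CPM in each library. They are thus log2(CPM + offset) relative to each library's own total over the listed genes, with no further scaling factor. The offset corresponds to 3.0 reads at the mean depth of 26130000 reads.

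Depth was estimated from the step, taken as what 1 read is worth, that makes the most low values whole multiples of it. The estimated totals over the listed genes were 21530000 to 30060000 reads per library. Of the values under 3 CPM, 34.9% to 48.7% per library were whole reads within 0.001, so whole reads were not recovered, and the count models planned for such a case (edgeR and DESeq2) were not used. Levels of a few reads carry counting error on top of the spread between libraries.

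The test was fixed before the data were examined, for linear normalized values with a pseudocount of 1 and a filter of at least 10 in at least 5 libraries. Since the values are log2 CPM already, limma 3.58.1 in R 4.3.3 was run on them as deposited, with lmFit and eBayes with a mean-variance trend, the group as the only term, two-sided p and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter, taken in reads at the mean depth, removed 0 of 14450 genes, since every listed gene had at least 10.22 reads in at least 5 libraries. Genes below such a level may thus have been left out of the table before it was deposited. Fold changes are on the log2(CPM + offset) scale, which understates the change of low genes. CPM means and SDs were computed after removing the offset.

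Gene lists were also fixed before the data were examined. Of 32 lists, 30 had at least 5 measured members and were tested with camera with a preset correlation of 0.01. The call was checked with a correlation estimated for each list and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. Members were also adjusted over the list alone. Isotype shares were taken within the sum of 7 heavy chain constant genes and compared with exact two-sided permutation tests over all assignments of the libraries to groups.

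The genes named were Chat, every measured isotype, up to 4 members with the smallest p of each list that passed or that bears on cell identity, and 12 genes in each direction. The last were to be those with the largest change among genes past the threshold, with a mean of at least 50 reads in the higher group and no overlap between groups. Since 0 such genes had a usable name, the genes with the smallest p were taken and are given as values that did not pass. Predicted genes, unnamed identifiers and receptor V, D and J segments were skipped, 1 among the higher and 4 among the lower. Gm48111, Gm48113 and genes called only when a library was left out were named after their values were seen. The same holds for the members Tbx21, Slc44a2, Ache, Prdm1, Xbp1, Irf4, Sdc1, Cd5, Spn and Itgam. It also holds for the acetylcholine receptor genes and the stromal and macrophage genes in the closing part.

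Symbols were matched for 14374 of 14450 gene identifiers, and coordinates were taken from GENCODE M21 (GRCm38). Shared sequence was measured as the percent of a gene's 31-base words found in transcripts of other genes. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

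The gene test was tested on simulated data drawn from a negative binomial with the means and within-group spread of the real genes, with 50 genes changed at each fold size. It called 54% of genes changed 2-fold, 62% at 4-fold, 92% at 8-fold and 96% at 16-fold, all in the right direction, and 12 of 14250 unchanged genes. All these genes were changed in the same simulated data, which makes the adjusted threshold easier to pass, and no simulated library stood apart. The shares called may thus be too high for the real libraries, where Chat, at 12.5-fold, missed the threshold. With the B-1 list raised 1.5-fold in simulated data, that list passed and 0 other lists did. Both simulations drew each gene independently, so members of a list did not move together as they can in the real libraries. They thus do not show how often lists pass by chance there, where other splits of the libraries called a median of 5 lists.

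The alternatives were other pseudocounts, a stricter filter, TMM and quantile scaling, the replicate number as a block, library quality weights, no mean-variance trend, and leaving out each library in turn. Limma-voom on reads estimated from the values, a pseudocount of 1 on the read scale, leaving out 3 libraries, the block without Chat- replicate 4 and an exact test of list means were added after the data were seen.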

Results

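RNA was sequenced from mature B cells sorted by flow cytometry from the bone marrow of unchallenged Chat-GFP mice, a reporter strain in which green fluorescence marks cells that use the Chat locus. Chat encodes choline acetyltransferase, the enzyme that makes acetylcholine. The series holds 5 libraries of Chat+ B cells and 5 libraries of Chat- B cells, and the comparison asks which transcripts differ between reporter-positive and reporter-negative mature B cells. The table lists 14450 genes as log2 CPM (counts per 1000000 counts), and the depth estimated from its low values was 21530000 to 30060000 reads per library. The labels do not say whether the 5 libraries of a group came from separate animals, so all p-values measure only the spread between these libraries.

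The libraries were alike in depth (26270000 ± 1980000 reads in Chat+ and 26000000 ± 3330000 in Chat-, mean ± SD, n = 5 each), but the library Chat- replicate 4 stood apart in composition. It had 1213 genes at the lowest value of the table, against 62 to 169 in the other Chat- libraries and 145 to 682 in the Chat+ libraries. Its mitochondrial transcripts made up 11.9% of the CPM, against 2.3% to 3.9% in the other 9 libraries.

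**Figure D1:**
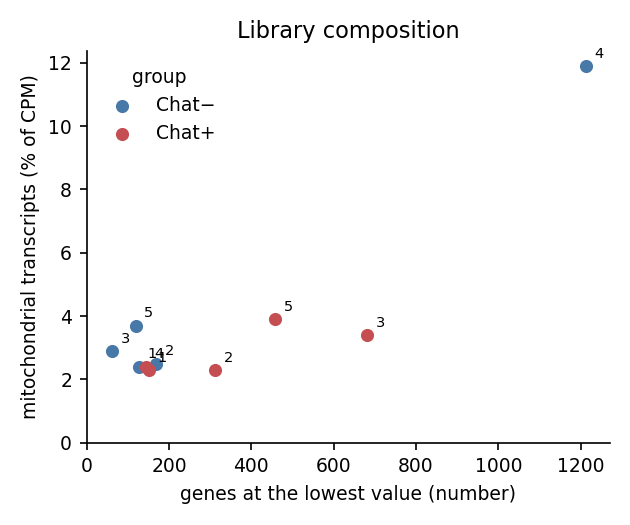
Number of genes at the lowest value of the table (x axis) and percent of CPM from mitochondrial genes (y axis) for each library, with colour giving the group and the small numbers the replicate. Chat- replicate 4 lies at 1213 genes and 11.9%, and no other library exceeds 682 genes or 3.9%.

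Chat transcript was higher in every Chat+ library than in any Chat- library. Since the groups were sorted by the Chat reporter, this is a check of the sort and the labels. It averaged 70.6 ± 28.9 CPM in Chat+ (31.1 to 111 CPM) and 7.5 ± 7.25 CPM in Chat- (1.17 to 19.7 CPM), both SD with n = 5. The fold difference on the log2(CPM + offset) scale was 12.5 (95% confidence interval 5.13 to 30.3; log2 fold change 3.64 ± 0.59, SE). The Chat- libraries were not free of the transcript, with a mean that was 10.6% of the Chat+ mean. Whether it came from Chat- cells or from Chat+ cells in that sort cannot be told from pooled cells. The gene (ENSMUSG00000021919, protein coding) lies on chromosome 14 at 32408203 to 32465989 on the minus strand of GRCm38.

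Chat separated the groups in an exact two-sided permutation test (p = 0.0079, the smallest value that the assignments of the libraries to groups can give). Over all 14450 genes it missed the threshold (limma, adjusted p = 0.087), while it passed when adjusted over the list alone, the 11 measured genes of acetylcholine synthesis, transport and breakdown (adjusted p = 4.6e-04). Without Chat- replicate 3, the Chat- library with the highest level, it passed over all genes (adjusted p = 0.023). It also passed with library quality weights (adjusted p = 0.014) and with the replicate number as a block (log2 fold change 3.64 ± 0.29, SE, adjusted p = 0.0092). The replicates ranked in the same order by Chat level (3, 1, 2, 4, 5) in both groups, an order seen after the test. Over all genes, 3 of 5 Chat+ libraries correlated best with the Chat- library of their own number (own-number correlations of -0.2 to 0.23). The labels do not say whether equal numbers mark the same animal, so pairing is neither shown nor excluded. Over all alternatives run, the adjusted p of Chat lay between 6.8e-04 and 0.30.

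**Figure D2:**
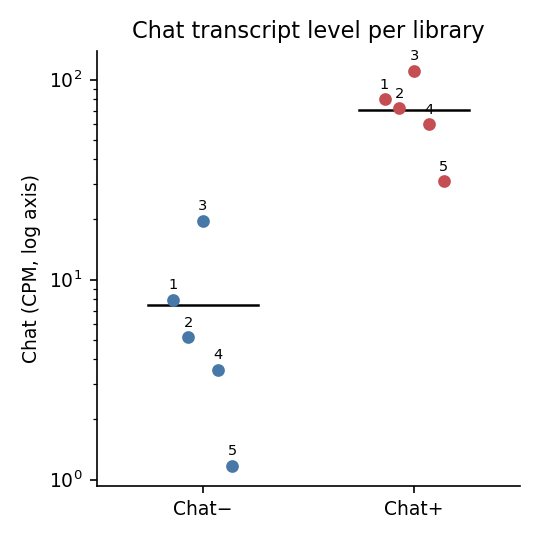
Chat level in CPM (y axis, log scale) in the 5 Chat- and 5 Chat+ libraries, each point a library numbered by its replicate, with a horizontal line at the group mean. The Chat+ libraries lie between 31.1 and 111 CPM, all above the Chat- maximum of 19.7 CPM.

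Across the genome, the genes with the strongest evidence for a higher level in Chat+ cells included cell cycle genes, a phosphatase and a costimulatory ligand, but none of them passed the adjusted threshold. Mki67, the gene of the proliferation antigen Ki-67, had 111 ± 28.9 CPM in Chat+ and 45.8 ± 8.81 CPM in Chat- (SD, n = 5; log2 fold change 1.25 ± 0.20, SE, adjusted p = 0.087). Ptpn22, a tyrosine phosphatase that restrains antigen receptor signalling, had 83.2 ± 11.5 against 46.5 ± 6.35 CPM (adjusted p = 0.087). Cd80, a costimulatory ligand carried by activated and memory B cells, had 10.4 ± 2.05 against 2.36 ± 1.03 CPM (adjusted p = 0.16).

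The other higher genes named by the same ranking were Krt222, Cdc42bpb and Emb (adjusted p = 0.087 each) and Nusap1, Ahnak, Nid1, Tpx2 and Rrm2 (adjusted p = 0.11 each), with log2 fold changes from 0.62 for Ahnak to 1.52 for Emb. All of these had every Chat+ library above every Chat- library. In the other direction, Rag1, a recombinase of developing lymphocytes, had 1.05 ± 0.659 CPM in Chat+ and 4.74 ± 1.92 CPM in Chat- (adjusted p = 0.34). Col5a3, Serinc5 and Cox6a2 came before it in rank, with log2 fold changes of -2.27, -0.73 and -2.87 and adjusted p of 0.22, 0.23 and 0.24. Hcrtr2, Slc25a47, Cd7, Cplx2, Dusp6, Rfx5, Rgl1 and Satb1 followed, with adjusted p of 0.35 to 0.56.

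With limma and Benjamini-Hochberg adjustment, 1 of 14450 genes passed, with 0 genes higher and 1 lower in Chat+. This was Gm48111 (ENSMUSG00000113388), a processed pseudogene on chromosome 13 at 65404296 to 65408136, named here after its value was seen. Its level was 0.0876 ± 0.196 CPM in Chat+ and 18.2 ± 11.7 CPM in Chat- (SD, n = 5; log2 fold change -6.59 ± 0.62, SE, adjusted p = 0.0021). Of its 31-base words, 98.7% also occur in transcripts of other genes, so its value is uncertain, and since 4 of the 5 Chat+ libraries are listed at 0 its fitted change depends on the offset. At an unadjusted p under 0.05 there were 651 genes, 505 higher and 146 lower, where chance gives 722.5. The 5 Chat+ libraries lay above all Chat- libraries for 162 genes and below them for 44, together 1.43% of genes against 0.79% by chance.

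The count of genes depended on the model and on single libraries. With library quality weights, 105 genes passed (93 higher and 12 lower in Chat+), and with the replicate number as a block 6 genes passed (5 higher). With limma-voom on estimated reads 0 genes passed, against 652 at an unadjusted p under 0.05, and Gm48111 lost its call (log2 fold change -8.62, adjusted p = 0.54). Without Chat- replicate 4, 6 genes passed, and these were Gm48111, Cd80, Ptpn22, Krt222, Ighg3 and Sirpa, all but the first higher in Chat+. Without Chat+ replicate 5, 6 genes passed, namely Gm48111 and the cell cycle genes Mki67, Top2a, Nusap1, Kif11 and Tpx2. Without Chat- replicate 1 or Chat- replicate 3, 2 genes passed, Gm48111 with Gm48113 in the first case and with Chat in the second.

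Genes typical of B-1 and other innate-like B cells rose together in Chat+ cells. B-1 cells are a self-renewing B cell class that secretes natural antibody. All 15 measured members of the list were higher in Chat+, with a median log2 fold change of 0.76, and 9 of the 15 rose when adjusted over the list alone (0 over all genes tested). Cd5, Spn and Itgam, also on the list, did not pass over the list alone (limma adjusted p = 0.11, 0.24 and 0.53). Zbtb32, a transcription factor of innate-like and memory B cells, had 13.7 ± 7.34 CPM in Chat+ and 2.86 ± 1.35 CPM in Chat- (SD, n = 5; log2 fold change 2.19 ± 0.42, SE). Bhlhe41, a transcription factor required by B-1a cells, had 45.0 ± 19.3 against 17.3 ± 4.66 CPM, Plac8 264 ± 50.2 against 168 ± 28.6 CPM and Ahnak 619 ± 74.9 against 402 ± 33.4 CPM. Zbtb32 lies on chromosome 7 at 30589681 to 30598909 and Bhlhe41 on chromosome 6 at 145858243 to 145865558.

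The list mean was 5.15 ± 0.13 log2 CPM in Chat+ (5.01 to 5.29) and 4.28 ± 0.21 in Chat- (3.98 to 4.48), so the groups did not overlap. The list passed with camera (adjusted p = 4.0e-16), and it was the 1 list of the 9 past the threshold that also passed when its correlation was estimated (adjusted p = 0.0099 with an estimated correlation). The directional test fry gave an adjusted p of 0.0025, while an exact permutation test of the list means reached its smallest p, 0.0079, and missed the threshold over 30 lists (adjusted p = 0.079). Markers of stromal and endothelial cells moved with this group when Chat- replicate 4 was left out. Their list was then higher in Chat+ (camera adjusted p = 1.2e-04, median log2 fold change 1.26), as was the monocyte and macrophage list (adjusted p = 0.0059). Exact permutation tests of these list means without that library gave unadjusted p = 0.032 and 0.087. With Chat- replicate 4 kept, the stromal list also passed with limma-voom and without Chat+ replicate 4. Library quality weights, which can count a library that stands apart less, called both the stromal list and the monocyte and macrophage list.

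Genes of the memory and age-associated B cell list also rose as a group. Of 18 measured members, 14 were higher in Chat+, and 4 rose when adjusted over the list alone (0 over all genes tested), namely Cd80, the integrin gene Itgb1, the transcription factor gene Zbtb20 and the intermediate filament gene Vim, which the B-1 list also holds. Itgb1 had 81.2 ± 15.7 CPM in Chat+ against 55.3 ± 8.64 CPM in Chat-, and Zbtb20 128 ± 21 against 89.4 ± 18.8 CPM (SD, n = 5). Tbx21, the transcription factor gene that defines age-associated B cells, had 3.59 ± 1.37 against 4.06 ± 1.43 CPM and did not pass. The list passed with camera (adjusted p = 5.2e-04) and with fry (adjusted p = 0.037), but not when its correlation was estimated (adjusted p = 0.17 with an estimated correlation) or with the exact test of list means (adjusted p = 0.079). Without Chat- replicate 4, the stromal and endothelial list (camera adjusted p = 1.2e-04) and the monocyte and macrophage list (0.0059) were higher in Chat+ along with this list (2.0e-06), and Itgb1 and Vim are also widely expressed in stromal cells.

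Cell cycle genes were higher in Chat+ cells. Of the 26 measured members of the proliferation list, 25 were higher, with a median log2 fold change of 0.65, and 13 rose when adjusted over the list alone (0 over all genes tested). Rrm2, a subunit of ribonucleotide reductase, had 39.3 ± 11.9 CPM in Chat+ and 17.8 ± 1.88 CPM in Chat- (SD, n = 5). The topoisomerase gene Top2a had 107 ± 30.2 against 49.7 ± 8.63 CPM, and Cdk1, the kinase that drives mitosis, 12.1 ± 3.11 against 4.72 ± 1.89 CPM. The members that did not pass over the list alone had log2 fold changes of -0.12 to 0.66.

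The proliferation list had the smallest camera p of the 30 lists (adjusted p = 6.5e-21), but its members move together between libraries and the call was lost when this was estimated (adjusted p = 0.15 with an estimated correlation). Fry gave an adjusted p of 0.029, and the exact test of list means 0.14. The list mean was 5.01 ± 0.34 log2 CPM in Chat+ and 4.32 ± 0.17 in Chat-, and Chat+ replicate 5, at 4.43, lay inside the Chat- range of 4.14 to 4.50. Without Chat- replicate 4, this list was also higher in Chat+ with camera (adjusted p = 1.2e-16). The stromal and endothelial list (1.2e-04) and the monocyte and macrophage list (0.0059) were higher there as well.

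**Figure D3:**
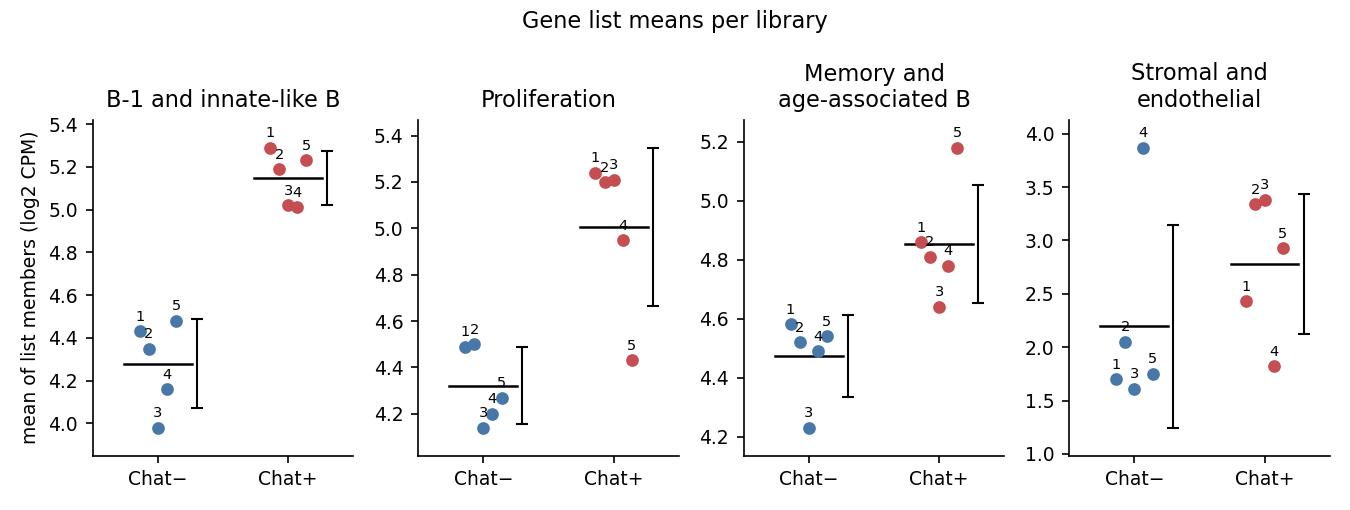
Mean log2 CPM of the members of 4 gene lists (y axes, each with its own range) in each library, with points numbered by replicate, a line at the group mean and a bar of 1 SD to each side. The B-1 means do not overlap between groups, Chat+ replicate 5 lies inside the Chat- range for proliferation, and Chat- replicate 4 has the highest stromal mean, 3.87.

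Antibody heavy chain usage differed between the groups. Among transcripts of the 7 measured heavy chain constant genes, the share of Ighd (IgD, carried by naive follicular B cells) was 24.3% ± 3.93 in Chat+ and 32.1% ± 2.93 in Chat- (SD, n = 5), and that of Ighm (IgM) was 74.1% ± 3.55 against 67.1% ± 2.86. The share of Ighg3 was 0.309% ± 0.119 against 0.0469% ± 0.0332, and that of Ighg2b 0.325% ± 0.119 against 0.165% ± 0.0303. These 4 shares passed an exact permutation test with Benjamini-Hochberg adjustment over 7 isotypes (adjusted p = 0.028 each). Igha, with 0.806% ± 0.376 against 0.407% ± 0.313, did not (adjusted p = 0.18), nor did Ighg1 (adjusted p = 0.70) and Ighg2c (adjusted p = 0.44).

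The IgG and IgA constant genes together made up 1.62% ± 0.66 of the constant transcripts in Chat+ and 0.778% ± 0.306 in Chat- (SD, n = 5; exact two-sided permutation p = 0.032). Whether these transcripts came from cells that had switched class was not tested. Transcripts of Ighg2b share 9.3% of their 31-base words with other genes and those of Ighg3 3.6%, so small shares of their reads are of uncertain origin. With 7 shares and few libraries, leaving out Chat- replicate 1, 2 or 4 left 0 shares past the threshold, and leaving out Chat- replicate 5 left 3. With Ighd left out of the sum, the Ighm share no longer passed and its difference changed sign (-0.972 percentage points, adjusted p = 0.095). The list of heavy chain genes rose with camera (adjusted p = 0.030; adjusted p = 0.21 with an estimated correlation), with 3 of its 7 members raised when adjusted over the list alone (Ighg2b, Ighg3 and Igha; 0 over all genes tested). This list did not pass without Chat+ replicate 5 (adjusted p = 0.25), Chat- replicate 1 (0.077) or Chat- replicate 3 (0.10), nor without the mean-variance trend (0.060) or with fry (0.17).

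**Figure D4:**
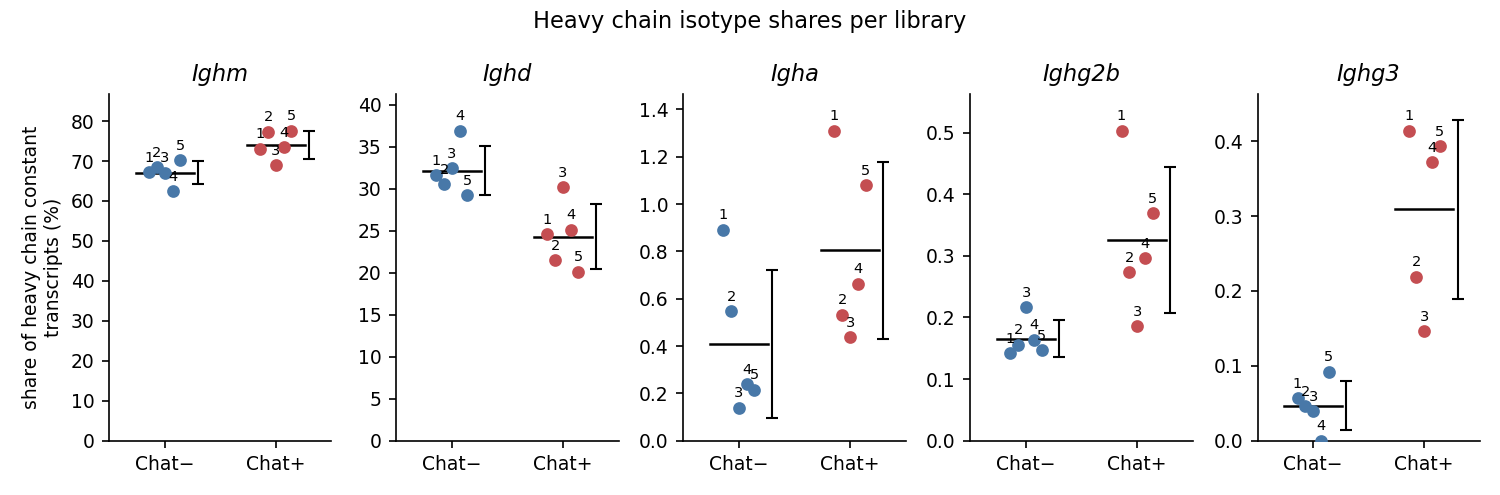
Share of each heavy chain constant gene among the 7 measured ones, in percent (y axes, each starting at 0 with its own range), in each library, with points numbered by replicate, a line at the group mean and a bar of 1 SD to each side. Every Chat+ library has more Ighg3 (0.146% to 0.414%) than any Chat- library (at most 0.0922%).

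Plasma cell genes were shifted slightly upward in Chat+ cells, with 12 of 16 measured members higher and a median log2 fold change of 0.11. Adjusted over the list alone, 0 members passed. The members Prdm1, Xbp1, Irf4 and Sdc1 hardly differed (log2 fold changes of 0.10, -0.01, -0.02 and -0.05). Jchain, which joins IgM and IgA chains into polymers, had 97.0 ± 85.6 CPM in Chat+ and 22.7 ± 9.40 CPM in Chat- (SD, n = 5). Derl3 and Mzb1, genes of the secretory pathway, had 4.23 ± 1.66 against 1.68 ± 0.947 CPM and 182 ± 24.1 against 132 ± 40.5 CPM. The list mean was 5.37 ± 0.15 log2 CPM in Chat+ (5.25 to 5.62) and 5.04 ± 0.13 in Chat- (4.82 to 5.15). Fry gave an adjusted p of 0.029, while the exact test of list means missed the threshold (adjusted p = 0.079). The list passed with camera (adjusted p = 0.035; adjusted p = 0.17 with an estimated correlation). It did not pass without Chat+ replicate 5 (adjusted p = 0.27) or Chat- replicate 1, 2 or 3 (0.081, 0.050 and 0.087), nor with TMM scaling (0.051), without the mean-variance trend (0.063) or without the 3 libraries that stood apart (0.11). Without Chat- replicate 4, the plasma cell list was higher in Chat+ with camera (adjusted p = 0.0059). The stromal and endothelial list (1.2e-04) and the monocyte and macrophage list (0.0059) were higher there as well.

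Lists of naive and developing B cells fell in Chat+ cells by small amounts. Of 17 measured genes of mature follicular B cells, 13 were lower, with a median log2 fold change of -0.06 (camera adjusted p = 5.1e-04; adjusted p = 0.21 with an estimated correlation and 0.26 with fry). Fcer2a, the gene of CD23, had 763 ± 102 CPM in Chat+ and 966 ± 50.3 CPM in Chat-, and Satb1 had 156 ± 17.9 against 200 ± 20.3 CPM (SD, n = 5), and 0 genes passed when adjusted over the list alone. This list did not pass with the replicate block without Chat- replicate 4 (adjusted p = 0.063). Of 10 measured genes of immature and precursor B cells, 9 were lower, with a median of -0.37 (camera adjusted p = 0.0018; adjusted p = 0.21 with an estimated correlation and 0.23 with fry). Rag1 fell when adjusted over the list alone (adjusted p = 0.014; 0 genes over all genes tested), and Kit, at 1.11 ± 0.716 against 0.362 ± 0.436 CPM, was the 1 member that was higher.

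Apart from Chat, the measured genes of the acetylcholine pathway showed no detectable difference. The choline transporter-like gene Slc44a2 had 371 ± 21.9 CPM in Chat+ and 373 ± 28.8 CPM in Chat- (SD, n = 5), and Ache, the gene of the enzyme that breaks acetylcholine down, had 0.483 ± 0.445 against 0.271 ± 0.25 CPM. The list of 11 measured genes did not pass with camera (adjusted p = 0.27). The list was fixed with 16 genes, and Slc18a3, Slc5a7 and Bche were among those that the table does not list. Since low genes may have been left out of the table, their absence may mean a low level. Of 21 acetylcholine receptor genes, the table lists 3, Chrna1, Chrnb1 and Chrnb2, at means of 0.477 to 11.2 CPM. None of these 3 receptor genes passed.

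Of the 8 lists of other bone marrow cells, 1 passed over all libraries in the main fit. Over the same libraries, library quality weights also called the stromal and endothelial, monocyte and macrophage, and erythroid lists as higher in Chat+. Such weights can count a library that stands apart less. Limma-voom also called the stromal list as higher, and the replicate block the megakaryocyte and platelet list as lower. Some members had high levels in both groups, such as the globin gene Hbb-bs, at 278 ± 68.6 CPM in Chat+ and 288 ± 125 CPM in Chat- (SD, n = 5). The dendritic cell list fell in Chat+ (camera adjusted p = 0.015; adjusted p = 0.15 with an estimated correlation, 0.029 with fry and 0.18 with the exact test of list means). Cox6a2, at 0.00775 ± 0.0173 against 0.833 ± 0.408 CPM, was the 1 of 12 members that fell when adjusted over the list alone (0 over all genes tested). This list did not pass without Chat+ replicate 3 (adjusted p = 0.057) or Chat+ replicate 4 (0.059), nor with the replicate block without Chat- replicate 4 (0.11). Siglech, a marker of plasmacytoid dendritic cells, had 1.37 ± 0.709 CPM in Chat+ and 4.33 ± 2.14 CPM in Chat- (SD, n = 5). Whether dendritic cells were carried into the Chat- sort was not tested. The mitochondrial genome list, a measure of sample quality, was lower in Chat+ (camera adjusted p = 1.2e-04; adjusted p = 0.52 with an estimated correlation), and this call ended without Chat- replicate 4 (adjusted p = 0.67).

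The other 21 lists did not pass with camera over all libraries in the main fit, with adjusted p from 0.057 to 0.83. For stromal and endothelial cells the adjusted p was 0.13, for monocytes and macrophages 0.83, for neutrophils and granulocytes 0.27, for T and NK cells 0.23 and for erythroid cells 0.83. B cell receptor signalling (adjusted p = 0.71), MHC class II antigen presentation (0.55), interferon-stimulated genes (0.20) and Toll-like receptors (0.83) did not pass either. The median log2 fold change and the direction of the test differed in sign for T and NK cells (median 0.18, mean -0.37, test down), B cell receptor signalling, monocytes and macrophages, and Toll-like receptors, and the mean did for MHC class II (median -0.03, mean 0.12, test down). Without Chat- replicate 4, the B cell receptor signalling and NF-kB target lists passed as lower in Chat+ with camera at the preset correlation (adjusted p = 0.047 and 0.020), with 0 members past the threshold adjusted over the list alone, and exact two-sided permutation tests of their list means gave p = 0.14 and 0.28.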

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

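Of the explanations weighed in this part, the test for cells of another type was chosen after the values had been seen, as was the reading of the read number test by how many genes thinning added, while the tests on read number, starting molecules and shared sequence were written down before their results. In 134 checks of the libraries of a group, 18 found a library far from the other 4, where chance gives 6.7 (about 1 check in 20), and 10 of the 18 concern Chat- replicate 4.

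Chat- replicate 4 had 1213 genes at the lowest value (at most 169 in the other Chat- libraries), 11.9% mitochondrial transcripts (at most 3.7%) and a mitochondrial list mean of 12.18 log2 CPM (at most 10.32). Its list means were the lowest of the group for B cell receptor signalling (8.21), MHC class II presentation (8.40) and glycolysis (5.38), and the highest for monocytes and macrophages (3.37) and for stromal and endothelial cells (3.87). Its log2 CPM was -0.57 for Cd80, against 1.37 to 1.66 in the other Chat- libraries, and 7.88 for Satb1, against 7.53 to 7.62.

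Fewer reads alone do not account for Chat- replicate 4: thinned to the same 18970000 reads outside the mitochondrial genome, no other library had more than 710 genes at 0, against 1213. The bound written beforehand, 606.5 genes, was not met, but it overlooked that Chat+ replicate 3 had 683 genes at 0 before thinning, and thinning added at most 27 genes to any library. Few starting molecules may have contributed: of genes with a median of 10 to 30 reads in the other libraries, 36.8% were at 0 and 28.5% exceeded 3 times the median, against at most 25.6% and 14.7% elsewhere. Cells of another type that passed the sort for mature B cells also stay open, since 80% of the stromal list, 75% of the monocyte and macrophage list and 60% of the T and NK list (3 of 5 genes, though its list mean of -0.29 was below the 0.41 of Chat- replicate 1) had their maximum in this library, against 22.1% of all genes and 7.1% to 23.1% of the other 5 lists of other cells. Among their abundant genes, Col1a1 had 111 CPM (7.59 to 42.4 in the other 9 libraries), Col1a2 99.2 CPM (7.82 to 34) and Lyz2 87.4 CPM (16 to 51.4), while Pecam1, which B cells also express, had 177 CPM (247 to 284).

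The pseudogenes Gm48111 and Gm48113 differed in opposite directions. Gm48111 was at the lowest value in all Chat+ libraries except replicate 2 (log2 CPM -0.86), and Gm48113 (4.80 ± 0.87 higher in log2, adjusted p = 0.14 with limma) was at the lowest value in all Chat- libraries except replicate 1 (1.61), with its Chat+ maximum of 3.63 in replicate 2. Reads shared with near-identical sequences may lie behind this pattern, since at least 96.3% of the 31-base words of each transcript occur in other genes, 230 of them for Gm48111 and 14 for Gm48113. A sequence difference between animals was not tested, and no biological explanation was tested.

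The remaining values are single libraries in single measures. Chat+ replicate 5 had the lowest list means of its group for immature and precursor B cells (1.09, next 1.76) and for B cell receptor signalling (8.35, next 8.52), and was the only Chat+ library with Cox6a2 above the lowest value (-2.70 log2 CPM). Chat- replicate 3 had a memory and age-associated list mean of 4.23 (next 4.49). Cd7 was at -1.48 log2 CPM in Chat+ replicate 4, and the next highest Chat+ library was at -2.73.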

How the results depend on the processing

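The block without Chat- replicate 4, voom, the pseudocount of 1, leaving out 3 libraries and the exact test of list means were chosen after seeing the data. The count of 1 gene held with pseudocounts of 0.5, 1 and 10, a stricter filter (11574 genes), TMM and quantile scaling, and moved to 105 genes (93 higher) with library quality weights, 3 without trend, 0 with voom (652 at an unadjusted p under 0.05), 17 without Chat+ replicates 3 and 5 and Chat- replicate 4, and 1 to 6 over the libraries left out in turn. The correlations of deviations between libraries of equal number were 0.23, 0.07, -0.06, -0.20 and 0.14, and 3 of 5 correlate best with their own number. Numbers 3 and 4 do not, and they hold Chat+ replicate 3 and Chat- replicate 4, which stand apart. Whether the numbers pair the samples thus cannot be told. As a block the numbers gave 6 genes, and 82 without Chat- replicate 4. Chat stayed higher throughout (log2 fold change 3.13 to 4.12 with libraries left out) and passed with the block (3.64, adjusted p = 0.0092), the block without Chat- replicate 4 (3.54) and weights (3.15, adjusted p = 0.014); over leave-outs its adjusted p was 0.023 to 0.30. Against 9 lists, 7 to 13 passed over leave-outs and 15 with weights; 1 passed with an estimated correlation, 6 with fry (5 of the 9) and 0 with the exact test of list means, whose smallest p was reached by 3 lists. The mitochondrial list turned to a median of 0.02 in the block without Chat- replicate 4. Of 4 isotype shares, 2 passed without Ighd in the sum, where the Ighm share turned to -0.972 points (adjusted p = 0.095), 0 with sign flips within numbers, which 5 pairs cannot bring under the threshold, and 0 to 4 over leave-outs. For these moves the cause was not tested. Of the named genes' values, 498 kept their side of the threshold, 48 newly passed and 1 no longer did; no gene changed sign. Leaving out the filter removes nothing and is the same fit; count models were not run.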

Other observations

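Of the tests in this part, those on splits for the lists without Chat- replicate 4, on precursors, on the share of B-1-like cells and on stromal cells or macrophages were chosen after the result was seen. Marginal zone B cell genes, a list that shares Cd9, Fcrl5 and Mzb1 with other lists here, were mostly higher in Chat+ cells. Of 13 measured members, 9 were higher, and 3 rose when adjusted over the list alone (Cd9, Fcrl5 and Cd36; 0 over all genes tested). Cd36, a scavenger receptor gene, had 44.9 ± 5.08 CPM in Chat+ and 34.5 ± 4.77 CPM in Chat- (SD, n = 5), and Fcrl5, an Fc receptor-like gene of innate-like B cells, 47.6 ± 35.0 against 15.9 ± 9.96 CPM. The list did not pass with camera (adjusted p = 0.091) and passed with fry (adjusted p = 0.0036).

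Germinal centre genes did not pass as a group (camera adjusted p = 0.28), and Mki67 was the 1 of 12 members that rose when adjusted over the list alone (0 over all genes tested). Bcl6, the transcription factor gene that defines germinal centre B cells, had 98.6 ± 17.9 CPM in Chat+ and 112 ± 10.7 CPM in Chat- (SD, n = 5). S1pr2 had 2.22 ± 0.515 against 1.63 ± 0.818 CPM.

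The counts of calls were set against those from other splits of the same libraries. Of 100 splits of the 10 libraries into 5 and 5, 11 gave as many genes as the real 1 (highest other 2), and 12 gave as many lists as the real 9 (highest other 12, median 5), so chance is not excluded for either. Without Chat- replicate 4, only the real split of 100 (1 of 100) gave 6 genes, with at most 3 in the others, and 4 of 100 gave as many lists as the real 12, with 14 as the highest other. At an unadjusted p under 0.05, 14 of 100 gave as many genes as the real 1058. Few splits matched the calls, but that library was singled out from these same data, so chance is not excluded here either. Some splits called far more genes at an unadjusted p under 0.05 than the real 651, up to 2676, which points to structure among the libraries other than the groups.

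For the higher B-1 and proliferation lists, with camera at the preset correlation both lists also passed without Chat- replicate 4 (larger adjusted p 7.3e-16), though over all libraries the proliferation list did not with an estimated correlation (0.15), and neither list did with the exact test of list means (B-1 0.079, proliferation 0.14). Cycling precursors in the Chat+ sort stay open: the precursor list was lower in Chat+ (median log2 fold change -0.37), but several members lie near the lowest value and its call was lost with an estimated correlation (adjusted p = 0.21). A hypothesis is that a larger share of B-1-like cells may account for the B-1 list. The mature follicular list was lower (median log2 fold change -0.06), which passed with camera at a preset correlation (adjusted p = 5.1e-04) and not with an estimated one (0.21). This cannot decide the hypothesis, since a small added share of such cells need lower that list only slightly. Stromal cells or macrophages in the Chat+ sort could bring Vim, S100a6, Anxa2 and Ahnak, yet the 1 Chat- library with both marker lists above all Chat+ libraries had a B-1 mean of 4.16, below the Chat+ minimum of 5.01, and 1 library does not exclude them. A change within the same B cell class, as a difference between the sorted groups, also stays open and was not tested.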
